A study of Drosophila melanogaster with 56 samples.

How the data were processed

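Expression was measured on 56 one-colour Affymetrix Drosophila arrays, 1 per sample, from 6 pools of flies sampled at 0, 24 and 48 h of fasting and divided into antenna, maxillary palp with proboscis, head and body. Per the labels, total RNA was extracted with Qiagen RNeasy, amplified with NuGEN Ovation RNA Amplification V2 and labelled with the FL-Ovation cDNA Biotin Module V2. The authors processed the arrays with GCRMA, whose version is not given in the sources used here, and the deposited values are log2 signals. The values showed a shared distribution on all arrays, with a largest difference of 0.033 between sorted arrays, so quantile scaling over all body parts was already in them. A change in the total RNA of a sample cannot be read from such values.

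The array held 18952 probe sets, of which 183 controls were left out. Probe sets with no gene (4720) or several genes (402) were counted and not named. Each of 11983 genes was read from its probe set of highest mean over all arrays, which gave 17104 features. Within a body part, a feature was tested when its log2 signal was at least 4 on at least 4 arrays. The body 48 h array whose title and source name gave different replicate numbers was named by its title.

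Differences between times were tested with limma 3.58.1 in R 4.3.3, with a fit per body part, 3 group means, a two-sided moderated test per feature and Benjamini-Hochberg adjustment over the features tested, at an adjusted p of 0.05. Differences between body parts in the change with time came from a single fit of 12 group means over 56 arrays, and unfasted differences from the 0 h arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The pool numbers pair the arrays across times, but the design text does not say that pools were used as a block, so the main tests had none. The pairing is incomplete: pool 9 gave only 0 h arrays (head replicate 5 among them), pool 7 none at 0 h, pool 6 no antenna at 0 h, and pool 5 no 48 h array outside antenna. With the pool as a fixed block, pool 9 therefore adds nothing to a difference between times. The pairing was checked on residuals: the mean correlation of arrays of the same pool was 0.12 in antenna, 0.13 in palp, 0.20 in head and 0.11 in body, against -0.02, -0.03, -0.04 and -0.02 for other pools.

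Lists of genes were compared with all other tested genes by limma's camera with a preset correlation of 0.01, adjusted over 240 tests of 32 lists, and again with an estimated correlation. The lists covered odorant, gustatory and ionotropic receptors, odorant-binding proteins, phototransduction, insulin signalling, lipolysis, fatty acid synthesis, glycolysis, gluconeogenesis, digestive enzymes, ribosomal proteins, ribosome biogenesis, immune effectors, yolk and eggshell, accessory gland, testis, ovary, heat shock, clock, cytochromes P450, glutathione transferases, neuropeptides, oxidative phosphorylation, proteasome, autophagy, cell cycle, muscle, fat body, glia, neurons and hemocytes. A list was tested where at least 3 of its members were. Counts adjusted over the list alone used the members' p values only.

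Genes were named by a rule. It took the largest rises and falls among called genes whose arrays did not overlap between times, up to 4 members per list, a fixed set of feeding and energy genes whatever their result, the largest differences between body parts, and the extremes of the unfasted comparisons. The samples, tests, lists, naming rule and the other settings listed first below were fixed before the data were examined. Genes changed in all 4 parts, and mag in head, were singled out after their values were seen.

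The tests were tried on simulated data drawn with each feature's mean and spread, with shifts of 0.5, 1 and 2 log2 units added to a few features at 48 h. They recovered 38.8%, 80.6% and 97% of the shifted genes in antenna, 46.3%, 83.6% and 89.4% in palp, 32.8%, 71.6% and 98.5% in head and 28.4%, 65.7% and 93.9% in body. False calls made up 7.7%, 7.6%, 6.9% and 3.8% of all calls.

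The results were recomputed with no filter on dim probe sets, quantile scaling again, the pool as a fixed or a random block, a single fit over all arrays, every probe set tested, array weights, and leaving out each array in turn. Cyclic loess scaling, the 3′ minus 5′ signal of eIF-4a, GAPDH and Act5C control transcripts as a covariate, the gut level (the mean of Jon65Aiii, Mal-A1, Mal-A6 and alphaTry) as a covariate, and leaving out 5 set-aside arrays were added after the data were seen. These 5, with gut or accessory gland transcripts or a wide residual spread, were 0 h replicate 2 of antenna, palp and head, and 24 h replicates 1 of antenna and 2 of palp. The accessory gland median covered 28 listed genes. Single-value comparisons used two-sided exact permutation tests. Raw image files were not used here.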

Results

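Adult Drosophila were compared before and during fasting, and the question put by the labels was how the transcripts of chemosensory organs, head and body change as food is withheld. Transcript levels were measured on 56 expression arrays, 1 per sample, in antenna, in maxillary palp with proboscis (palp hereafter), in head and in body at 0, 24 and 48 h of fasting. The groups held 4, 5 and 5 arrays in antenna and 5, 5 and 4 in each other part. No fed flies were sampled at 24 or 48 h, so fasting cannot be told from age or elapsed time. Values were log2 signals from 2.08 to 15.4, and every array had a median of 4.04. Between 32.8% and 38.3% of probe sets per array lay at the lowest value, and 50.1% reached 4. A value with ± is a log2 difference with its standard error from limma; "rose" and "fell" are used for differences past an adjusted p of 0.05. A number alone in brackets after a list is its adjusted p, and a second is that with an estimated correlation. A fold given as a lower bound belongs to a gene below 4 on every array of the lower group.

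The unfasted comparison asked which transcripts each dissection held. In antenna, Obp59a (11.37 ± 0.66, at least 838-fold), which encodes an odorant-binding protein, and GstE4 (11.28 ± 0.26, at least 1102-fold), a glutathione transferase, stood above head, and the insulin-like peptide gene Ilp2 (-10.88 ± 1.05, at least 522-fold) stood below it (n = 4 and 5). Odorant receptors were higher in antenna for 38 of 44 tested (median 6.56), as were 15 of 17 ionotropic receptors (median 4.65), and 13 of 14 phototransduction genes were lower (median -3.70). In palp, CG14277 (11.30 ± 0.89), CG3088 (11.19 ± 1.12) and CG8329 (10.93 ± 1.12) led the genes above head, with 10 of 14 gustatory receptors (median 2.86), 27 of 39 odorant-binding proteins (median 2.26) and 14 of 17 muscle genes (median 1.70) higher (n = 5 and 5). In body, the accessory gland genes Acp53Ea (12.54 ± 0.71, at least 1704-fold) and Acp98AB (12.44 ± 1.14, at least 1487-fold) stood highest above head, and the photoreceptor channel gene trp (-12.64 ± 0.37, at least 1819-fold) stood lowest (n = 5 and 5). All 27 accessory gland genes, 17 of 18 testis genes and 34 of 38 digestive enzymes were higher in body, and all 14 phototransduction genes were lower (median -11.11). Of 11203 features, 5485 differed between antenna and head (2963 higher, 2522 lower), 6040 between palp and head (3444 higher, 2596 lower) and 9625 between body and head (3516 higher, 6109 lower). On every 0 h array, 35 of 57 odorant receptors reached 4 in antenna and 11 in palp; the numbers were 36 and 9 at 24 h, and 35 and 10 at 48 h.

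In antenna, the main olfactory organ, 48 h against 0 h asked what changed. The lipophorin receptor gene LpR1 (3.46 ± 0.21) rose, as did dyw (3.84 ± 0.69), Bcat (3.30 ± 0.29), which encodes the branched-chain amino acid aminotransferase, CG34265 (2.82 ± 0.39) and CG7059 (2.82 ± 0.18). The storage protein gene Lsp2 (-8.56 ± 0.91) fell most, followed by the odorant-binding protein genes Obp99b (-6.78 ± 0.41) and Obp56a (-4.20 ± 0.31), phu (-4.47 ± 0.73), and Npc2h (-4.37 ± 0.55) of the Niemann-Pick type C2 family. In total 1580 of 8986 features changed in limma (n = 5 and 4). Of these 774 rose and 806 fell, 119 and 240 by at least 2-fold. The arrays of both times did not overlap for 1568 features, 17.4% of those tested, where chance gives 1.59%. Without the 0 h array of replicate 4, 1046 features passed.

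As a list, odorant-binding proteins fell (adjusted p = 0.00453, and 0.498 with an estimated correlation). Of 30 tested, 7 fell and 1 rose (7 and 2 adjusted over the list alone). Oxidative phosphorylation genes, as a group, fell (adjusted p = 4.01e-07, and 0.5 with an estimated correlation). Of 58 tested, 10 fell and 1 rose (13 and 1 adjusted over the list alone, and 2 to 7 called without any 1 of 0 h replicates 2 and 4 and 48 h replicates 1, 2 and 5), among them ND-B14.5A (-0.86 ± 0.20) of complex I. Glutathione transferases fell as a list (adjusted p = 0.000643, and 0.498 with an estimated correlation). Of 33 tested, 11 fell and 1 rose (13 and 2 adjusted over the list alone, and 5 to 7 called without any 1 of 0 h replicates 2, 3 and 4 and 48 h replicates 1, 3 and 5). As a list, lipolysis and fatty acid oxidation genes fell (adjusted p = 0.0183, and 0.575 with an estimated correlation). Of 16 tested, 6 fell and 1 rose (9 and 1 adjusted over the list alone). CRAT (-0.66 ± 0.15), the carnitine acetyltransferase gene, fell. Antimicrobial and immune effector genes, as a group, fell (adjusted p = 0.0217, and 0.633 with an estimated correlation). Of 16 tested, 8 fell and 2 rose (8 and 3 adjusted over the list alone, and 4 to 6 called without any 1 of 0 h replicate 2 and 48 h replicates 1, 2, 3 and 5), with PGRP-SB1 (-3.53 ± 0.42) and Drsl4 (-3.57 ± 0.48) lowest. Hemocyte genes fell as a list (adjusted p = 0.0272, and 0.575 with an estimated correlation). Of 13 tested, 5 fell (5 adjusted over the list alone), including the prophenoloxidase genes PPO1 (-3.05 ± 0.40) and PPO2 (-1.88 ± 0.31). As a list, fat body genes fell (adjusted p = 0.00857, and 0.494 with an estimated correlation). Of 7 tested, 3 fell (4 adjusted over the list alone), including apolpp (-1.87 ± 0.24), the apolipophorin gene. Autophagy genes, as a group, rose (adjusted p = 0.0118, and 0.498 with an estimated correlation). Of 19 tested, 5 rose (7 adjusted over the list alone, and 3 called without 0 h replicate 2), including Atg101 (0.61 ± 0.12). Insulin signalling and FOXO-responsive genes rose as a list (adjusted p = 0.0255, and 0.559 with an estimated correlation). Of 8 tested, 4 rose and 1 fell (5 and 1 adjusted over the list alone). InR (2.15 ± 0.34), the insulin receptor gene, rose and ImpL2 (-2.26 ± 0.23) fell. As a list, neuron genes rose (adjusted p = 0.0353, and 0.575 with an estimated correlation). Of 11 tested, 2 rose (5 adjusted over the list alone, and 0 or 1 called without any 1 of 0 h replicates 2, 3 and 4 and 48 h replicates 1, 2, 3, 5 and 6). The odorant receptor list was not called (adjusted p = 0.119), and 2 of 36 members were, Or59b (-0.65 ± 0.10) lower and Or42a (1.72 ± 0.46, at least 1.86-fold) higher (1 and 1 adjusted over the list alone). The Or42a call was lost without any 1 of 0 h replicates 1 and 4 (adjusted p up to 0.056, with 1 member called without replicate 4), with the pool as a block (0.12) and with no filter on dim probe sets (0.062). The antimicrobial (0.305), neuron (0.056) and hemocyte (0.189) lists were not called with the pool as a block. The odorant receptor (0.0435) and phototransduction (0.0395) lists were called only with the pool as a block. The antimicrobial call was lost without 0 h replicate 4 (0.178). The neuron call was lost without any 1 of 0 h replicate 4 and 48 h replicate 1 (up to 0.164). The hemocyte call was lost without 0 h replicate 4 (0.111).

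In palp and proboscis, which taste food and smell it at close range, 48 h against 0 h asked the same. The largest rises were in Pgant4 (9.41 ± 0.23, at least 368-fold), a polypeptide N-acetylgalactosaminyltransferase gene, CG14949 (7.16 ± 0.52, at least 61.9-fold), the lipase gene mag (6.46 ± 0.30, at least 34.6-fold), the lysozyme gene LysS (5.88 ± 0.80, at least 15.5-fold) and hll (5.82 ± 0.18, at least 36-fold). The largest falls were in Lsp2 (-6.55 ± 0.81), fit (-6.41 ± 0.62), CG17290 (-5.85 ± 0.42, at least 19.8-fold), CG7227 (-5.41 ± 0.46, at least 17-fold) and the drosomycin-like gene Drsl4 (-5.07 ± 0.52). In total 2986 of 9031 features changed in limma (n = 4 and 5). Of these 1572 rose and 1414 fell, 344 and 346 by at least 2-fold.

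Ribosome biogenesis genes, as a group, rose (adjusted p = 0.000171, and 0.56 with an estimated correlation). Of 30 tested, 17 rose (19 adjusted over the list alone), led by Non1 (1.20 ± 0.09). Autophagy genes rose as a list (adjusted p = 0.000322, and 0.494 with an estimated correlation). Of 19 tested, 12 rose (14 adjusted over the list alone), with Atg18b (1.73 ± 0.23) and the kinase gene Atg1 (1.35 ± 0.17) in front. As a list, insulin signalling and FOXO-responsive genes rose (adjusted p = 0.00136, and 0.498 with an estimated correlation). Of 8 tested, 5 rose (7 adjusted over the list alone), with InR (2.45 ± 0.24) and chico (1.31 ± 0.11), the insulin receptor substrate gene, among them. Odorant-binding proteins, as a group, fell (adjusted p = 3.4e-05, and 0.522 with an estimated correlation). Of 32 tested, 16 fell (17 adjusted over the list alone, and 9 or 10 called without any 1 of 48 h replicates 1 and 4), including Obp56b (-4.06 ± 0.50) and Obp44a (-2.89 ± 0.63). Glutathione transferases fell as a list (adjusted p = 0.000171, and 0.56 with an estimated correlation). Of 30 tested, 15 fell (16 adjusted over the list alone), including GstD4 (-2.86 ± 0.50). As a list, lipolysis and fatty acid oxidation genes fell (adjusted p = 0.0107, and 0.494 with an estimated correlation). Of 15 tested, 7 fell and 1 rose (8 and 1 adjusted over the list alone), with the peroxisomal acyl-CoA oxidase gene Acox57D-d (-1.09 ± 0.23) among those that fell. Antimicrobial and immune effector genes, as a group, fell (adjusted p = 0.00966, and 0.575 with an estimated correlation). Of 19 tested, 8 fell and 1 rose (9 and 1 adjusted over the list alone), though AttD (3.52 ± 0.91, at least 3.43-fold) rose. Hemocyte genes fell as a list (adjusted p = 0.0183, and 0.583 with an estimated correlation). Of 13 tested, 6 fell (6 and 1 adjusted over the list alone), with PPO1 (-2.37 ± 0.27) and PPO2 (-1.93 ± 0.27) lower. Within lists that were not called, the receptor genes Or1a (-2.61 ± 0.42) and Or45b (-2.36 ± 0.36, at least 2.39-fold) fell and Ir56d (1.03 ± 0.26) rose. The phototransduction (0.033) and glycolysis (0.0363) lists were called only with the pool as a block. The hemocyte call was lost without 0 h replicate 5 (0.0593).

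In head, 48 h against 0 h asked what changed. The largest rises were in CG7763 (6.58 ± 0.48, at least 46.5-fold), CG14949 (6.30 ± 0.65, at least 24.2-fold), hll (6.09 ± 0.27, at least 47.1-fold), Ama (6.02 ± 0.37, at least 25.9-fold), which encodes an immunoglobulin-domain protein, and Mdr50 (4.97 ± 0.52), an ABC transporter gene. The largest falls were in Obp99b (-7.46 ± 0.70), fit (-7.43 ± 0.75), Drsl4 (-5.95 ± 0.59), CG43673 (-5.73 ± 0.94) and CG7227 (-5.31 ± 0.31, at least 14.1-fold). Among hormone genes, Ilp5 (-5.21 ± 0.44), which encodes an insulin-like peptide of the brain, fell, the drop in Ilp2 (-0.61 ± 0.14) was smaller, and the adipokinetic hormone gene Akh (0.89 ± 0.21) rose. In a single fit over all arrays, Ilp2 (adjusted p = 0.61) and Akh (adjusted p = 0.46) were not called. In total 2318 of 9083 features changed in limma (n = 4 and 5). Of these 1199 rose and 1119 fell, 206 and 465 by at least 2-fold. With the pool as a block, 4524 features passed, and with array weights, 4550.

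As a list, glutathione transferases fell (adjusted p = 1.4e-06, and 0.498 with an estimated correlation). Of 27 tested, 16 fell (17 adjusted over the list alone), including GstE3 (-1.62 ± 0.18). Antimicrobial and immune effector genes, as a group, fell (adjusted p = 0.000135, and 0.56 with an estimated correlation). Of 18 tested, 8 fell (11 adjusted over the list alone). Lipolysis and fatty acid oxidation genes fell as a list (adjusted p = 0.000237, and 0.494 with an estimated correlation). Of 15 tested, 9 fell and 1 rose (9 and 1 adjusted over the list alone), with Acox57D-d (-2.44 ± 0.18) lowest. As a list, oxidative phosphorylation genes fell (adjusted p = 0.000322, and 0.575 with an estimated correlation). Of 56 tested, 5 fell (2 adjusted over the list alone, and 2 to 9 called without any 1 of 0 h replicates 1, 2, 3, 4 and 5 and 48 h replicates 2, 3 and 4), including UQCR-11L (-2.30 ± 0.37). Hemocyte genes, as a group, fell (adjusted p = 0.00101, and 0.498 with an estimated correlation). Of 13 tested, 7 fell (7 adjusted over the list alone), including PPO1 (-2.72 ± 0.38) and the phagocytic receptor gene eater (-1.78 ± 0.27). Cytochromes P450 fell as a list (adjusted p = 0.00234, and 0.498 with an estimated correlation). Of 64 tested, 22 fell and 10 rose (22 and 12 adjusted over the list alone). Cyp313a4 (3.35 ± 0.35, at least 3.39-fold) and Cyp6t3 (3.27 ± 0.27, at least 5.31-fold) rose. As a list, odorant-binding proteins fell (adjusted p = 0.0136, and 0.575 with an estimated correlation). Of 25 tested, 12 fell and 1 rose (12 and 1 adjusted over the list alone, and 8 called without any 1 of 0 h replicate 1 and 48 h replicate 4), including Obp99d (-3.03 ± 0.51). Proteasome genes, as a group, fell (adjusted p = 0.0175, and 0.575 with an estimated correlation). Of 26 tested, 5 fell (5 adjusted over the list alone, and 2 or 11 called without any 1 of 0 h replicates 1, 3, 4 and 5 and 48 h replicates 3 and 4). Fat body genes fell as a list (adjusted p = 0.022, and 0.494 with an estimated correlation). Of 7 tested, 4 fell (4 adjusted over the list alone), with Lsp2 (-5.26 ± 0.74) and fat-spondin (-0.75 ± 0.13) lower.

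As a list, insulin signalling and FOXO-responsive genes rose (0.00121, 0.494). Of 8 tested, 5 rose (6 adjusted over the list alone), with InR (2.24 ± 0.27) and the sestrin gene Sesn (1.07 ± 0.10) among them. Ribosome biogenesis genes, as a group, rose (adjusted p = 0.00305, and 0.575 with an estimated correlation). Of 30 tested, 10 rose (11 adjusted over the list alone, and 5 or 6 called without any 1 of 0 h replicates 1, 3 and 4 and 48 h replicates 1, 3 and 4), with Non1 (1.04 ± 0.11) and the fibrillarin gene Fib (0.85 ± 0.18). Autophagy genes rose as a list (adjusted p = 0.00603, and 0.494 with an estimated correlation). Of 18 tested, 8 rose (12 and 1 adjusted over the list alone, and 5 called without any 1 of 0 h replicate 2 and 48 h replicate 3), with Atg9 (1.24 ± 0.23) and Atg2 (0.79 ± 0.11) higher. The fat body (0.0726) list was not called with the pool as a block. No single array left out ended any list call made in head at 48 h. Among digestive enzymes, which were not called as a list in head at 48 h (adjusted p = 0.939), mag (4.92 ± 0.69) rose.

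In body, 48 h against 0 h asked what changed. The largest rises were in CG7763 (7.05 ± 0.63, at least 47.8-fold), CG11425 (6.63 ± 0.29), Dtd (5.72 ± 0.42, at least 29.5-fold), Sardh (5.41 ± 0.68), the sarcosine dehydrogenase gene, and Cyp6a2 (5.00 ± 0.38). The largest falls were in the gut protease gene Jon99Fi (-8.70 ± 0.96), CG17192 (-8.42 ± 0.43, at least 90.6-fold), Obp99b (-7.72 ± 0.83), Lsp2 (-7.37 ± 1.52) and Npc2d (-7.25 ± 0.62). In total 4742 of 9336 features changed in limma (n = 4 and 5). Of these 2782 rose and 1960 fell, 597 and 892 by at least 2-fold. With the 3′ minus 5′ signal of control transcripts as a covariate, 2519 features passed. After cyclic loess scaling, which moved the median log2 difference of all features from 0.103 to 0.013, 47.5% of the called features were higher, against 58.7% before it.

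As a list, male accessory gland genes fell (adjusted p = 2.9e-14, and 0.498 with an estimated correlation). Of 27 tested, 26 fell (26 adjusted over the list alone), including Acp53C14c (-2.93 ± 0.32) and Acp76A (-2.75 ± 0.33). Digestive enzymes, as a group, fell (1.48e-07, 0.498). Of 39 tested, 26 fell and 3 rose (27 and 3 adjusted over the list alone), with Jon25Bi (-6.86 ± 0.83) after Jon99Fi. Proteasome genes fell as a list (adjusted p = 2.19e-05, and 0.56 with an estimated correlation). Of 26 tested, 19 fell (20 adjusted over the list alone), including Prosalpha4 (-1.37 ± 0.20) and Rpn12 (-0.89 ± 0.16). As a list, glutathione transferases fell (adjusted p = 3.01e-05, and 0.498 with an estimated correlation). Of 28 tested, 16 fell (17 adjusted over the list alone), with GstE10 (-5.28 ± 0.57) and GstD5 (-3.46 ± 0.52) lowest. Odorant-binding proteins, as a group, fell (adjusted p = 0.000135, and 0.53 with an estimated correlation). Of 24 tested, 14 fell and 1 rose (14 and 1 adjusted over the list alone), including Obp56e (-6.91 ± 1.05, at least 46.1-fold). Lipolysis and fatty acid oxidation genes fell as a list (adjusted p = 0.00031, and 0.56 with an estimated correlation). Of 15 tested, 10 fell and 1 rose (10 and 1 adjusted over the list alone), with Acox57D-d (-3.89 ± 0.46) and CRAT (-1.84 ± 0.27) lower. As a list, cytochromes P450 fell (adjusted p = 0.00353, and 0.628 with an estimated correlation). Of 64 tested, 24 fell and 10 rose (24 and 10 adjusted over the list alone), with Cyp6t1 (-5.09 ± 0.47, at least 17.2-fold) lowest. Hemocyte genes, as a group, fell (adjusted p = 0.00534, and 0.56 with an estimated correlation). Of 11 tested, 8 fell and 1 rose (8 and 1 adjusted over the list alone), including PPO2 (-5.09 ± 0.86) and PPO1 (-4.11 ± 0.69). Oxidative phosphorylation genes fell as a list (adjusted p = 0.0274, and 0.844 with an estimated correlation). Of 72 tested, 15 fell and 12 rose (7 and 8 adjusted over the list alone, and 10 to 17 called without any 1 of 0 h replicates 3, 4 and 5 and 48 h replicate 1).

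As a list, antimicrobial and immune effector genes fell (adjusted p = 0.0285, and 0.583 with an estimated correlation). Of 18 tested, 6 fell and 2 rose (6 and 2 adjusted over the list alone), with Drsl4 (-5.93 ± 0.68) lowest. Fat body genes, as a group, fell (adjusted p = 0.0475, and 0.559 with an estimated correlation). Of 5 tested, 3 fell (3 adjusted over the list alone), including fat-spondin (-0.85 ± 0.19). Ribosome biogenesis genes rose as a list (adjusted p = 0.00337, and 0.628 with an estimated correlation). Of 26 tested, 11 rose (11 adjusted over the list alone), with mbm (1.43 ± 0.34) and ppan (1.31 ± 0.32) higher. As a list, insulin signalling and FOXO-responsive genes rose (adjusted p = 0.00418, and 0.498 with an estimated correlation). Of 8 tested, 5 rose (5 adjusted over the list alone), including InR (4.24 ± 0.34, at least 9.79-fold) and chico (1.71 ± 0.10). Autophagy genes, as a group, rose (adjusted p = 0.00456, and 0.56 with an estimated correlation). Of 19 tested, 14 rose (14 and 1 adjusted over the list alone), with Atg18b (2.52 ± 0.57) and Atg1 (1.99 ± 0.27) higher. Testis genes rose as a list (adjusted p = 0.00468, and 0.632 with an estimated correlation). Of 17 tested, 10 rose (13 adjusted over the list alone, and 5 or 6 called without any 1 of 48 h replicates 1 and 2). As a list, ovary and germline genes rose (0.0455, 0.498). Of 6 tested, 4 rose (5 adjusted over the list alone), with gcl (0.88 ± 0.14) higher. Unfasted yolk and eggshell genes were lower in body than in head (3 of 3, median -3.83), so this call does not show a change in ovary. The ovary (0.0554) and oxidative phosphorylation (0.203) lists were not called with the pool as a block. The fatty acid synthesis (0.0328) list was called only with the pool as a block. The fat body (0.24) list was not called with no filter on dim probe sets. The antimicrobial (0.0574), oxidative phosphorylation (0.0782) and fat body (0.0559) lists were not called after cyclic loess scaling. The antimicrobial call was lost without 48 h replicate 1 (0.0629). The ovary call was lost without any 1 of 0 h replicates 4 and 5 and 48 h replicates 1 and 2 (up to 0.0651). The oxidative phosphorylation call was lost without any 1 of 0 h replicates 3 and 5 and 48 h replicates 1 and 3 (up to 0.229). The fat body call was lost without any 1 of 0 h replicates 2, 3 and 4, 24 h replicates 1 and 3 and 48 h replicates 1 and 4 (up to 0.0719).

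**Figure D1:**
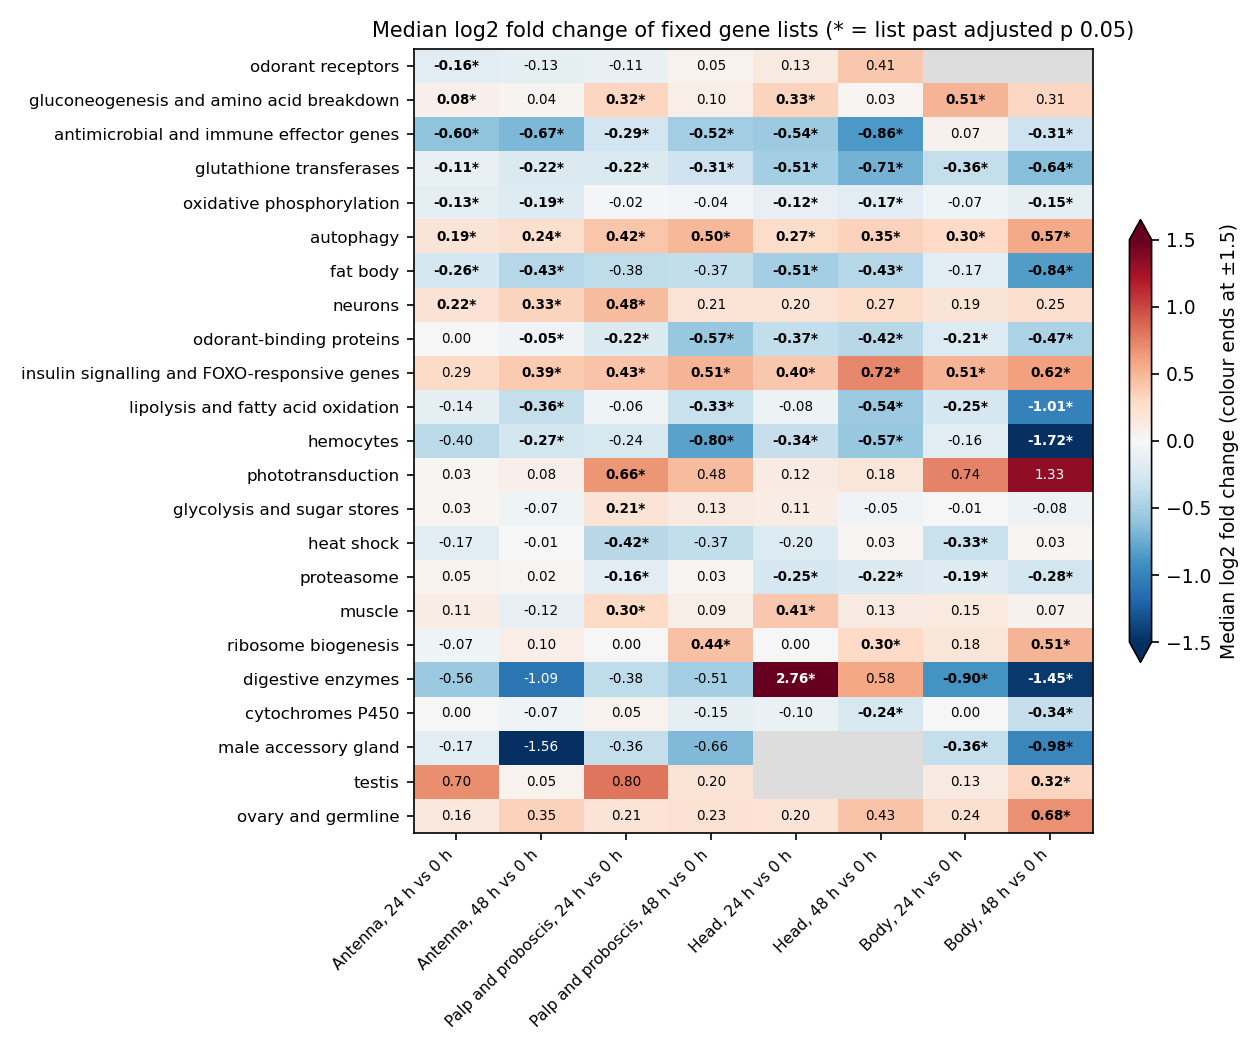
Median log2 difference of each gene list (lines of the grid) in each comparison with 0 h (columns), from -1.5 to 1.5 on the colour scale, with a star where the list was called and grey where fewer than 3 members were tested. The male accessory gland and digestive enzyme lists were called lower in body at both times, and the autophagy list was called higher in all 8 columns, in antenna at 24 h only with 0 h replicates 3 and 4 and 24 h replicate 1 kept (adjusted p up to 0.0949 without one). Of all 88 calls, 0 held with an estimated correlation.

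At 24 h the antenna was compared with 0 h to ask which changes came early. LpR1 (2.81 ± 0.21), hll (3.04 ± 0.38, at least 3.7-fold) and Sardh (2.61 ± 0.39) rose, and phu (-5.46 ± 0.73, at least 16.4-fold) and Obp99b (-5.41 ± 0.41) fell. The fall of Lsp2 (-5.02 ± 0.91) had an adjusted p of 0.052 with the pool as a block. In total 515 of 8986 features changed in limma (n = 5 and 4). Of these 232 rose and 283 fell, 47 and 107 by at least 2-fold. With the pool as a block, 273 features passed, and with array weights, 1101. The count was 278 to 299 without any 1 of 0 h replicate 4 and 24 h replicates 2 and 6. Of the lists called at 48 h, the autophagy (0.0285, 0.498) and neuron (0.0299, 0.575) lists rose at 24 h too. The antimicrobial (0.0223, 0.633), glutathione transferase (0.0267, 0.575), oxidative phosphorylation (4.64e-05, 0.575) and fat body (0.0299, 0.498) lists fell at 24 h too. Of the oxidative phosphorylation and neuron lists, 0 members were called in limma, with 13 and 3 at an unadjusted p under 0.05. Odorant receptors, as a group, fell (adjusted p = 0.0285, and 0.71 with an estimated correlation). Of 36 tested, 1 fell (1 adjusted over the list alone). Gluconeogenesis and amino acid breakdown genes rose as a list (adjusted p = 0.0329, and 0.498 with an estimated correlation). Of 13 tested, 3 rose (3 adjusted over the list alone). The antimicrobial (0.673), glutathione transferase (0.187) and fat body (0.0977) lists were not called with the pool as a block. The phototransduction (0.0299), insulin and FOXO (0.044) and muscle (0.0467) lists were called only with the pool as a block. The odorant receptor (0.463) and gluconeogenesis (0.208) lists were not called without the 5 set-aside arrays. The odorant receptor call was lost without any 1 of 0 h replicates 1 and 2 and 24 h replicates 1 and 3 (up to 0.177). The gluconeogenesis call was lost without any 1 of 0 h replicates 1 and 2 and 24 h replicate 1 (up to 0.169). The antimicrobial call was lost without any 1 of 0 h replicate 4 and 24 h replicate 3 (up to 0.362). The glutathione transferase call was lost without any 1 of 0 h replicates 2 and 4 and 24 h replicate 6 (up to 0.111). The autophagy call was lost without any 1 of 0 h replicates 3 and 4 and 24 h replicate 1 (up to 0.0949). The fat body call was lost without any 1 of 0 h replicates 1 and 3 and 24 h replicate 3 (up to 0.0686). The neuron call was lost without any 1 of 0 h replicate 4 and 24 h replicate 1 (up to 0.202).

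The palp comparison at 24 h asked the same. Pgant4 (7.11 ± 0.21, at least 74.5-fold), hll (6.97 ± 0.17, at least 79.5-fold) and mag (6.68 ± 0.29, at least 40.4-fold) rose most, and fit (-5.24 ± 0.59), CG17290 (-5.15 ± 0.39) and phu (-5.07 ± 0.78) fell most. In total 2124 of 9031 features changed in limma (n = 5 and 5). Of these 993 rose and 1131 fell, 180 and 227 by at least 2-fold. Of the lists called at 48 h, the insulin and FOXO (0.00234, 0.498) and autophagy (0.000322, 0.494) lists rose at 24 h too. The odorant-binding protein (0.0285, 0.635), antimicrobial (0.0285, 0.608) and glutathione transferase (0.00181, 0.575) lists fell at 24 h too. As a list, muscle genes rose (0.000194, 0.494). Of 17 tested, 8 rose (9 adjusted over the list alone, and 5 called without 24 h replicate 3). Glycolysis and sugar store genes, as a group, rose (0.00121, 0.498). Of 17 tested, 5 rose (6 adjusted over the list alone). Gluconeogenesis and amino acid breakdown genes rose as a list (0.00301, 0.498). Of 13 tested, 5 rose (7 adjusted over the list alone). As a list, phototransduction genes rose (0.0183, 0.633). Of 14 tested, 0 rose (0 adjusted over the list alone, with 3 at an unadjusted p under 0.05 in limma, and 1 or 3 called without any 1 of 0 h replicates 4 and 5). Neuron genes, as a group, rose (0.0378, 0.575). Of 10 tested, 1 rose (1 adjusted over the list alone, and 2 called without any 1 of 0 h replicates 4 and 5 and 24 h replicate 2). Proteasome genes fell as a list (adjusted p = 0.0222, and 0.575 with an estimated correlation). Of 26 tested, 5 fell (8 adjusted over the list alone, and 3 called without any 1 of 0 h replicate 3 and 24 h replicate 5). As a list, heat shock genes fell (0.0347, 0.575). Of 10 tested, 2 fell (2 adjusted over the list alone, and 4 called without any 1 of 0 h replicate 4 and 24 h replicate 5). The proteasome (0.257) list was not called with the pool as a block. The odorant-binding protein (0.113), phototransduction (0.0698) and antimicrobial (0.103) lists were not called without the 5 set-aside arrays. The odorant-binding protein call was lost without any 1 of 0 h replicate 2 and 24 h replicate 5 (up to 0.0785). The phototransduction call was lost without 0 h replicate 3 (0.0679). The antimicrobial call was lost without 0 h replicate 2 (0.0821). The heat shock call was lost without any 1 of 0 h replicates 2 and 3 and 24 h replicates 1 and 3 (up to 0.0794). The proteasome call was lost without 0 h replicate 5 (0.122). The neuron call was lost without any 1 of 0 h replicates 2 and 3 and 24 h replicate 1 (up to 0.114).

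In head at 24 h, CG16826 (7.40 ± 1.75), hll (6.98 ± 0.25, at least 86.8-fold) and whe (5.83 ± 1.56) rose most, and fit (-6.31 ± 0.70), phu (-5.52 ± 0.64), CG7227 (-4.84 ± 0.29) and Obp99b (-4.82 ± 0.66) fell. The rise of whe had an adjusted p of 0.054 without 0 h replicate 3 and of 0.055 with the 3′ minus 5′ signal as a covariate. Ilp5 (-3.21 ± 0.41) fell by 24 h. In total 1564 of 9083 features changed in limma (n = 5 and 5). Of these 683 rose and 881 fell, 159 and 249 by at least 2-fold. With the pool as a block 3987 features passed, with array weights 2832, and without 0 h replicate 5, 2659. Digestive enzymes, as a group, rose (0.00437, 0.575). Of 22 tested, 5 rose and 1 fell (7 and 1 adjusted over the list alone, and 13 called without 0 h replicate 2). Their largest rise was in mag (5.81 ± 0.65). The mean of 4 abundant gut transcripts was 7.98 ± 4.20 in head at 0 h (SD, n = 5), 12.25 ± 0.85 at 24 h (n = 5) and 9.46 ± 2.31 at 48 h (n = 4), against 14.11 ± 0.09 in body at 0 h. Its difference of 4.27 at 24 h had an exact two-sided permutation p of 0.0635 (adjusted p = 0.254 over 8 comparisons). Muscle genes rose as a list (0.00243, 0.575). Of 17 tested, 5 rose (7 adjusted over the list alone, and 3 called without 24 h replicate 2). As a list, gluconeogenesis and amino acid breakdown genes rose (0.00301, 0.498). Of 13 tested, 4 rose (5 adjusted over the list alone). Of the lists called at 48 h, the insulin and FOXO (0.00234, 0.494) and autophagy (0.00603, 0.494) lists rose at 24 h too. The odorant-binding protein (0.044, 0.633), antimicrobial (0.00146, 0.575), glutathione transferase (0.000196, 0.575), oxidative phosphorylation (0.038, 0.765), proteasome (0.00301, 0.56), fat body (0.0222, 0.494) and hemocyte (0.0293, 0.575) lists fell at 24 h too. The digestive enzyme (0.0725), oxidative phosphorylation (0.0744), fat body (0.0694) and hemocyte (0.0631) lists were not called with the pool as a block. The digestive enzyme (0.0882) list was not called with no filter on dim probe sets. The odorant-binding protein (0.0609) list was not called after cyclic loess scaling. The odorant-binding protein (0.051) and oxidative phosphorylation (0.0677) lists were not called without the 5 set-aside arrays. The odorant-binding protein call was lost without any 1 of 0 h replicates 1, 3 and 4 and 24 h replicates 4 and 5 (up to 0.121). The oxidative phosphorylation call was lost without any 1 of 0 h replicates 1, 2 and 5 and 24 h replicates 2, 4 and 5 (up to 0.161). The hemocyte call was lost without any 1 of 0 h replicate 5 and 24 h replicate 3 (up to 0.0728).

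In body at 24 h, CG7763 (7.27 ± 0.59, at least 55.6-fold), CG11425 (6.17 ± 0.27) and Sardh (5.56 ± 0.64) rose most, and CG17192 (-8.42 ± 0.40, at least 90.6-fold), Jon99Fi (-7.72 ± 0.90), phu (-7.50 ± 0.85, at least 54-fold) and Jon25Bi (-7.19 ± 0.78) fell most. In total 1977 of 9336 features changed in limma (n = 5 and 5). Of these 856 rose and 1121 fell, 250 and 429 by at least 2-fold. Without 24 h replicate 1, 3170 features passed, and with array weights, 3804. After cyclic loess scaling 32.9% of the called features were higher, against 43.3% before it. Of the lists called at 48 h, the insulin and FOXO (0.00305, 0.498) and autophagy (0.000823, 0.498) lists rose at 24 h too. The odorant-binding protein (0.0299, 0.633), lipolysis (0.0313, 0.633), digestive enzyme (5.78e-07, 0.498), male accessory gland (1.42e-06, 0.575), glutathione transferase (0.00085, 0.549) and proteasome (1.78e-05, 0.56) lists fell at 24 h too. Gluconeogenesis and amino acid breakdown genes, as a group, rose (0.00767, 0.56). Of 13 tested, 8 rose and 1 fell (8 and 1 adjusted over the list alone). Heat shock genes fell as a list (0.0274, 0.575). Of 13 tested, 5 fell (6 adjusted over the list alone, and 2 or 3 called without any 1 of 0 h replicates 1, 2 and 3 and 24 h replicates 2 and 3). The muscle (0.0052) list was called only with the pool as a block. The odorant-binding protein (0.181) list was not called with no filter on dim probe sets. The odorant-binding protein call was lost without any 1 of 0 h replicate 1 and 24 h replicate 5 (up to 0.108). The lipolysis call was lost without any 1 of 0 h replicate 4 and 24 h replicate 3 (up to 0.0561). The heat shock call was lost without any 1 of 0 h replicate 3 and 24 h replicate 1 (up to 0.0718).

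**Figure D2:**
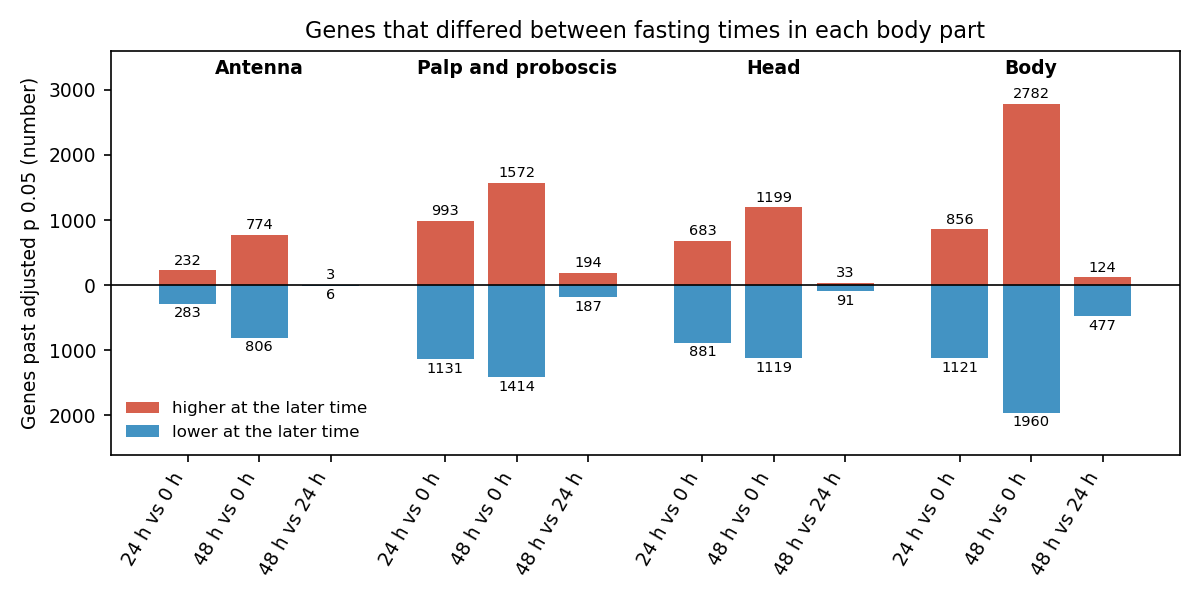
Number of features past an adjusted p of 0.05 in limma, higher and lower, for each body part and pair of times. Against 0 h the body had the most at 48 h (4742 of 9336) and the antenna the fewest at 24 h (515 of 8986).

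The comparison of 48 h with 24 h asked what changed during the second day. In head, CG12111 (3.19 ± 0.29, at least 4.74-fold) rose and Cyp4e3 (-3.05 ± 0.34) fell. In body, Dtd (3.42 ± 0.42) rose, and Cyp4e3 (-5.23 ± 0.53) and Obp99b (-5.93 ± 0.83) fell. In palp, CG34256 (2.37 ± 0.38) and CG10336 (2.34 ± 0.37) rose. The test passed 381 of 9031 features (194 higher, 187 lower) in palp, 124 of 9083 features (33 higher, 91 lower) in head and 601 of 9336 features (124 higher, 477 lower) in body. In antenna, where it passed 9 of 8986 features (3 higher, 6 lower), hll (-2.26 ± 0.36, at least 3.7-fold) fell, but its call was lost without any 1 of 24 h replicates 2, 4 and 6 and 48 h replicates 1, 2, 3, 5 and 6 (adjusted p up to 0.12) and with the pool as a block (adjusted p = 0.1). The counts in palp were 90 to 253 without any 1 of 24 h replicates 1 and 3 and 48 h replicates 1, 2 and 4, and 1765 with array weights. In head they were 34 to 82 without any 1 of 24 h replicates 1, 3 and 5 and 48 h replicates 1, 3 and 4, 511 with the pool as a block and 671 with array weights. In body they were 269 to 378 without any 1 of 24 h replicate 1 and 48 h replicates 1 and 4 and 919 without 48 h replicate 3, and 1569 in a single fit over all arrays. In antenna they were 38 with the pool as a random block, 45 with array weights, 49 in a single fit over all arrays and 0 to 3 without any 1 of 24 h replicates 2, 3, 4 and 6 and 48 h replicates 1, 2, 5 and 6, where 745 features had an unadjusted p under 0.05 in limma with all arrays.

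Both times share the 0 h arrays, so the correlation of their differences was set against simulated data in which nothing changed. Features called in the same direction at 24 and 48 h numbered 471, 1665, 1228 and 1692 in antenna, palp, head and body, where independent calls give 45.4, 349.9, 198.7 and 490.4. Across features, which are not independent replicates, the correlation of the differences at both times was 0.865, 0.824, 0.771 and 0.846, against 0.547, 0.476, 0.475 and 0.463 simulated. Their covariance was 0.2, 0.319, 0.343 and 0.652, against 0.0335, 0.0323, 0.0394 and 0.0397 simulated. With the 0 h arrays split so that the times shared none, the correlation was 0.625, 0.733, 0.533 and 0.795, and 67, 591, 303 and 621 features were called at both times, against 3.9, 75.8, 25.1 and 124.3 for independent calls. The simulated arrays were drawn independently, whereas arrays of both times came from the same pools, and neither comparison removes what the pools shared.

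The overlap between body parts asked which changes at 48 h were shared. The genes of the 4 largest minimum rises were InR (2.15 ± 0.34, 2.45 ± 0.24, 2.24 ± 0.27 and 4.24 ± 0.34 in antenna, palp, head and body), Sardh (2.10 ± 0.39, 2.34 ± 0.13, 2.50 ± 0.21 and 5.41 ± 0.68), CG10383 (2.79 ± 0.18, 3.38 ± 0.11, 4.08 ± 0.16 and 1.94 ± 0.28) and the calcium-binding protein gene CBP (2.31 ± 0.39, 1.92 ± 0.30, 2.90 ± 0.21 and 3.70 ± 0.50). They were followed by CG7763 (1.74 ± 0.45, 5.04 ± 0.32, 6.58 ± 0.48 and 7.05 ± 0.63), Pgant4 (2.37 ± 0.42, 9.41 ± 0.23, 1.63 ± 0.45 and 1.83 ± 0.21) and Pfas (1.63 ± 0.15, 2.83 ± 0.16, 2.82 ± 0.13 and 2.77 ± 0.33), a gene of purine synthesis. Of 7180 features tested in every part, 280 were higher in all 4 parts, where independent calls give 3.8, and 335 were lower, against 3.6. Palp and head shared 1408 calls in the same direction and 13 in opposite directions, against 347.1 and 346.3 for independent calls. Antenna and body shared 857 and 41, against 305.8 and 306.8. The arrays of the body parts came from the same pools of flies, so these calls were not made in independent animals.

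**Figure D3:**
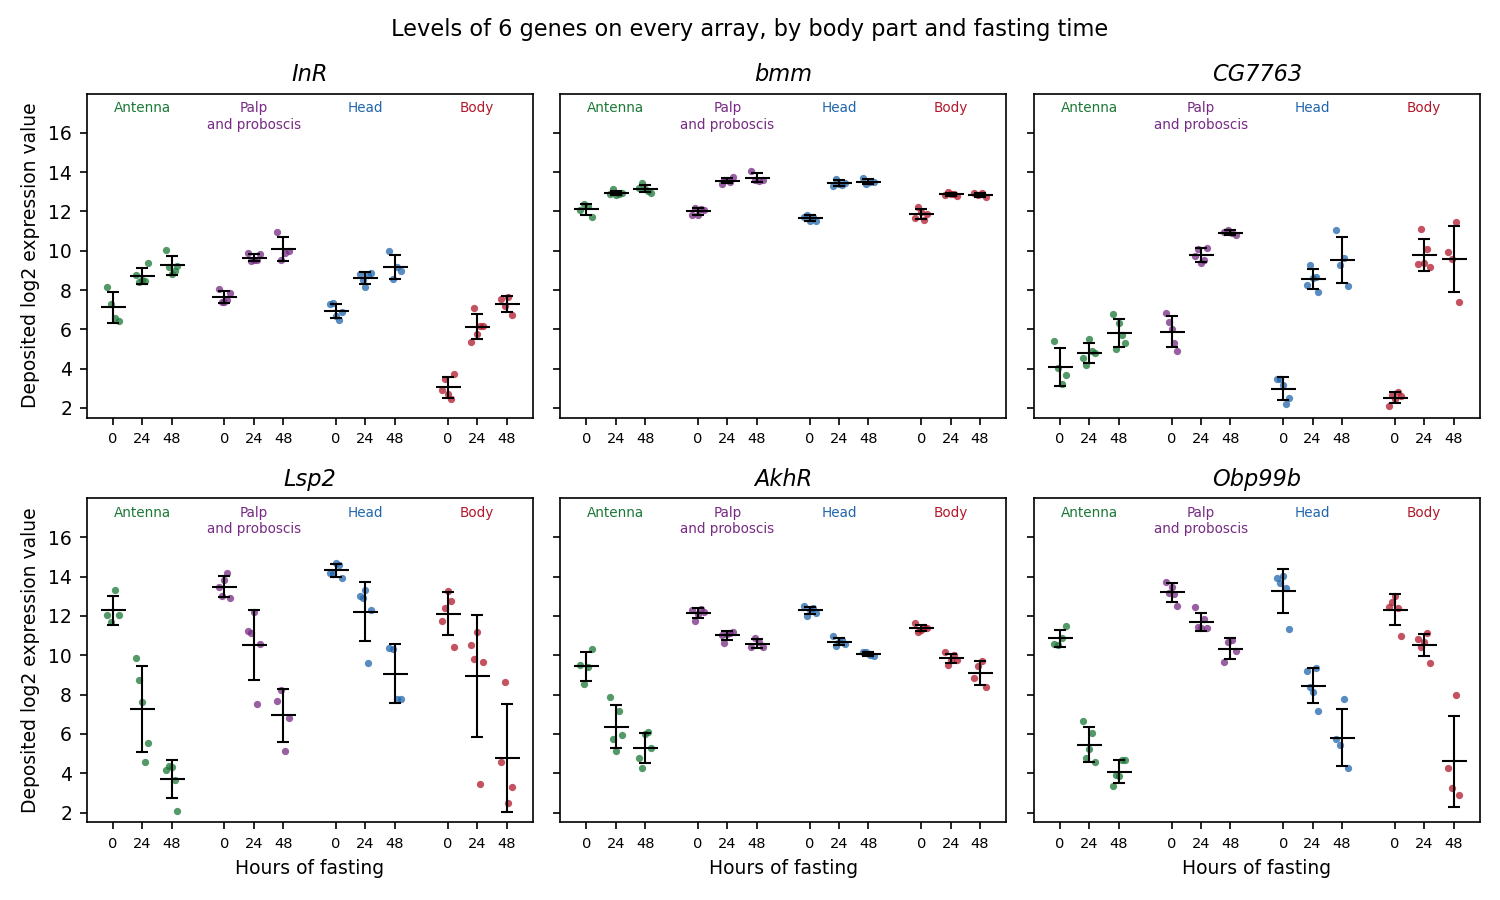
Log2 signal of InR, bmm, CG7763, Lsp2, AkhR and Obp99b on each array (points) by body part and hours of fasting, with the group mean and SD. InR was higher at 48 h than at 0 h in all 4 parts, by 2.15 in antenna and 4.24 in body.

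A direct test asked where the change with time differed between body parts. The rise of Ama in head, from 2.67 at 0 h to 8.69 at 48 h, had no counterpart past the threshold in antenna (2.19 and 2.30) or palp (2.23 and 2.26), and the difference of changes was -5.92 ± 0.29 for antenna minus head and -6.0 ± 0.29 for palp minus head. Antenna also differed from head in hll (-5.31 ± 0.50), which rose in head. Pgant4 rose more in palp than in head (7.79 ± 0.52) and than in antenna (antenna minus palp -7.04 ± 0.52). LysS differed in the same way (palp minus head 5.88 ± 0.60, antenna minus palp -5.88 ± 0.60). The lipase gene mag moved apart in body, where it went from 12.82 to 9.29, and head, where it went from 3.95 to 8.87 (body minus head -8.45 ± 0.79). Of 11522 features, 2687 passed the F test of interaction over all parts and times. At 48 h, 510 differed between antenna and head (310 with a higher and 200 with a lower change in antenna), 428 between palp and head (271 and 157), 2286 between body and head (1223 and 1063) and 514 between antenna and palp (192 and 322). Of these, 52, 53, 274 and 54 were lower at 48 h in 1 part and below 4 on all 0 and 48 h arrays of the other, where no fall could be seen. Lists were not tested for a difference between parts.

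Genes of feeding and energy control were followed whatever their result. The triglyceride lipase gene bmm rose at 48 h in every part, by 1.05 ± 0.13 in antenna, 1.71 ± 0.12 in palp, 1.87 ± 0.11 in head and 0.99 ± 0.12 in body, and at 24 h by 0.83 ± 0.13 in antenna, 1.57 ± 0.12 in palp, 1.78 ± 0.10 in head and 1.02 ± 0.11 in body. AkhR, the adipokinetic hormone receptor gene, changed by -4.15 ± 0.55 in antenna, -1.54 ± 0.15 in palp, -2.20 ± 0.12 in head and -2.30 ± 0.23 in body at 48 h, and by -3.08 ± 0.55 in antenna, -1.12 ± 0.14 in palp, -1.58 ± 0.11 in head and -1.55 ± 0.22 in body at 24 h. InR at 24 h changed by 1.60 ± 0.34 in antenna, 2.01 ± 0.23 in palp, 1.68 ± 0.25 in head and 3.07 ± 0.32, at least 4.35-fold in body, and without the 0 h array of replicate 4 the antennal value was 1.37 with an adjusted p of 0.056. Its adjusted p was 0.052 with no filter on dim probe sets. ACC, the acetyl-CoA carboxylase gene, rose in palp (0.61 ± 0.09) and head (0.51 ± 0.10) at 48 h and was not called in body (0.02 ± 0.14, adjusted p = 0.92). In antenna (0.36 ± 0.12) its adjusted p rounded to 0.05 and was not under it, and was 0.02 without 0 h replicate 3, 0.019 in a single fit over all arrays and 0.17 with the pool as a block. The neuropeptide F gene NPF fell in palp (-1.45 ± 0.23) and body (-1.85 ± 0.44) and was not called in antenna (-0.56 ± 0.40, adjusted p = 0.37) or head (-0.12 ± 0.10, adjusted p = 0.42). With the 3′ minus 5′ signal of control transcripts as a covariate, its body value was -0.87 with an adjusted p of 0.077. The short neuropeptide F receptor gene sNPF-R rose in palp (0.59 ± 0.14) and was not called in antenna (0.34 ± 0.23, adjusted p = 0.34) or head (0.36 ± 0.18, adjusted p = 0.15). Pepck1, a gluconeogenesis gene, fell in antenna (-0.97 ± 0.20) and was not called in palp (0.10 ± 0.11, adjusted p = 0.5), head (-0.05 ± 0.09, adjusted p = 0.7) or body (-0.07 ± 0.09, adjusted p = 0.55). Pepck2 was not called in any part at 48 h, with values from -1.09 ± 0.64, adjusted p = 0.26 in antenna to -0.07 ± 0.43, adjusted p = 0.9 in body. The odorant co-receptor gene Orco was not called in antenna (-0.18 ± 0.13, adjusted p = 0.38) or palp (0.17 ± 0.11, adjusted p = 0.25) at 48 h, nor were the sugar receptor gene Gr64f (0.11 ± 0.19, adjusted p = 0.7) and the bitter receptor gene Gr66a (0.05 ± 0.14, adjusted p = 0.83) in palp. The fatty acid synthase gene FASN1 was not called in antenna (-0.01 ± 0.10, adjusted p = 0.94), palp (-0.08 ± 0.10, adjusted p = 0.6) or head (-0.05 ± 0.09, adjusted p = 0.75).

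Other calls of these genes hung on single arrays. In body at 48 h these were Lip4 (-1.27 ± 0.44, adjusted p = 0.029, lost without any 1 of 0 h replicates 1 and 4 and 48 h replicates 2 and 4, at most 0.086), FASN1 (-0.35 ± 0.11, adjusted p = 0.021, lost without any 1 of 48 h replicates 1 and 4, at most 0.075) and sNPF (0.74 ± 0.27, adjusted p = 0.036, lost without any 1 of 0 h replicates 2, 3, 4 and 5 and 48 h replicates 2, 3 and 4, at most 0.11, and 0.16 with the pool as a block). In head they were Desat1 at 48 h (0.23 ± 0.08, adjusted p = 0.045, lost without any 1 of 0 h replicates 2, 3, 4 and 5 and 48 h replicates 1, 2, 3 and 4, at most 0.1, and 0.084 with the pool as a block) and Ilp2 at 24 h (-0.46 ± 0.14, adjusted p = 0.034, lost without any 1 of 0 h replicates 1, 2, 3 and 4 and 24 h replicates 2, 3 and 5, at most 0.08). In palp at 48 h the fructose receptor gene Gr43a (1.18 ± 0.35, adjusted p = 0.02) lost its call without the 48 h arrays of replicates 2 and 4 (adjusted p up to 0.052) and with the pool as a block (0.83, adjusted p = 0.12). Akh rose in body at 48 h (1.13 ± 0.30, adjusted p = 0.0093, and 0.28 in a single fit over all arrays), and its 24 h call there (0.87 ± 0.28, adjusted p = 0.046, lost without any 1 of 0 h replicates 1, 2 and 3 and 24 h replicates 2, 3, 4 and 5, at most 0.11) was weaker. Akh was not called in antenna (-0.01 ± 0.81, adjusted p = 0.99) or palp (0.40 ± 1.34, adjusted p = 0.85). The glucosidase gene tobi fell in antenna (-3.27 ± 0.68, adjusted p = 0.0059) and palp (-1.76 ± 0.44, adjusted p = 0.0075) and was not called in head (-1.86 ± 0.72, adjusted p = 0.072, and adjusted p = 0.014 with the pool as a block) or body (0.08 ± 0.19, adjusted p = 0.75).

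No call was made at either time for 9 lists, whose counts at 48 h follow. Gustatory receptors had 2 of 9 higher, 0 lower in antenna and 1 of 15 higher, 0 lower in palp, with adjusted p from 0.441 to 0.541. The count was 0 or 1 without any 1 of 0 h replicates 1, 2, 3 and 4 and 48 h replicates 2, 5 and 6 in antenna; 0 to 3 without any 1 of 0 h replicates 2 and 4 and 48 h replicates 2 and 4 in palp. Ionotropic receptors had 0 of 16 called in antenna (5 at an unadjusted p under 0.05 in limma), 1 of 5 higher, 0 lower in palp and 0 of 3 called in head (1 at an unadjusted p under 0.05 in limma), with adjusted p from 0.205 to 0.977. The count was 1 or 2 without any 1 of 0 h replicates 1 and 3 and 48 h replicates 2, 3 and 6 in antenna; 2 without 0 h replicate 5 in palp; 1 without any 1 of 0 h replicates 2 and 5 in head. In antenna, a single fit over all arrays called 7, array weights 5 and the pool as a random block 4. Fatty acid synthesis and lipid storage genes had 4 of 14 higher, 2 lower in antenna, 3 of 14 higher, 2 lower in palp, 4 of 15 higher, 5 lower in head and 2 of 14 higher, 8 lower in body, with adjusted p from 0.0513 to 0.973. The count was 3 without 0 h replicate 4 in antenna. Ribosomal protein genes had 1 of 35 higher, 0 lower in antenna, 3 of 34 higher, 0 lower in palp, 1 of 33 higher, 0 lower in head and 6 of 41 higher, 0 lower in body, with adjusted p from 0.0965 to 0.915. The count was 2 without any 1 of 0 h replicate 4 and 48 h replicate 2 in antenna; 2 without 0 h replicate 5 in head. Circadian clock genes had 0 of 8 higher, 1 lower in antenna, 2 of 8 higher, 2 lower in palp, 0 of 8 called in head (1 at an unadjusted p under 0.05 in limma) and 2 of 8 higher, 1 lower in body, with adjusted p from 0.695 to 0.932. The count was 2 without 0 h replicate 1 in antenna; 2 without any 1 of 48 h replicates 1 and 4 in palp; 1 without any 1 of 48 h replicates 1 and 4 in body. DNA replication and cell cycle genes had 1 of 10 higher, 0 lower in antenna, 2 of 12 higher, 1 lower in palp, 3 of 9 higher, 1 lower in head and 3 of 5 higher, 0 lower in body, with adjusted p from 0.28 to 0.967. The count was 0 or 2 without any 1 of 0 h replicates 2 and 3 and 48 h replicate 6 in antenna; 1 without 0 h replicate 2 in body. Glia genes had 1 of 8 higher, 0 lower in antenna, 1 of 9 higher, 1 lower in palp, 1 of 9 higher, 2 lower in head and 0 of 9 higher, 2 lower in body, with adjusted p from 0.238 to 0.972. The count was 0 without any 1 of 0 h replicates 3 and 4 and 48 h replicates 1 and 2 in antenna; 1 without any 1 of 48 h replicates 1 and 4 in body. Yolk and eggshell genes had 0 of 3 called in palp (0 at an unadjusted p under 0.05 in limma) and 0 of 4 called in head (0 at an unadjusted p under 0.05 in limma), with adjusted p from 0.639 to 0.721. Neuropeptide and receptor genes had 1 of 21 higher, 3 lower in antenna, 2 of 23 higher, 6 lower in palp, 2 of 29 higher, 8 lower in head and 2 of 15 higher, 5 lower in body, with adjusted p from 0.0765 to 0.627. Over all lists and comparisons, 88 of 240 tests were called, 32 up and 56 down, and 0 of these 88 calls held with an estimated correlation. Regrouping the times within each part gave up to 77 calls, so a single list call is weak evidence. The median, mean and test of a list differed in sign in 31 tests, none of them called, such as the ionotropic receptors in antenna and the heat shock genes in head at 48 h.

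**Figure D4:**
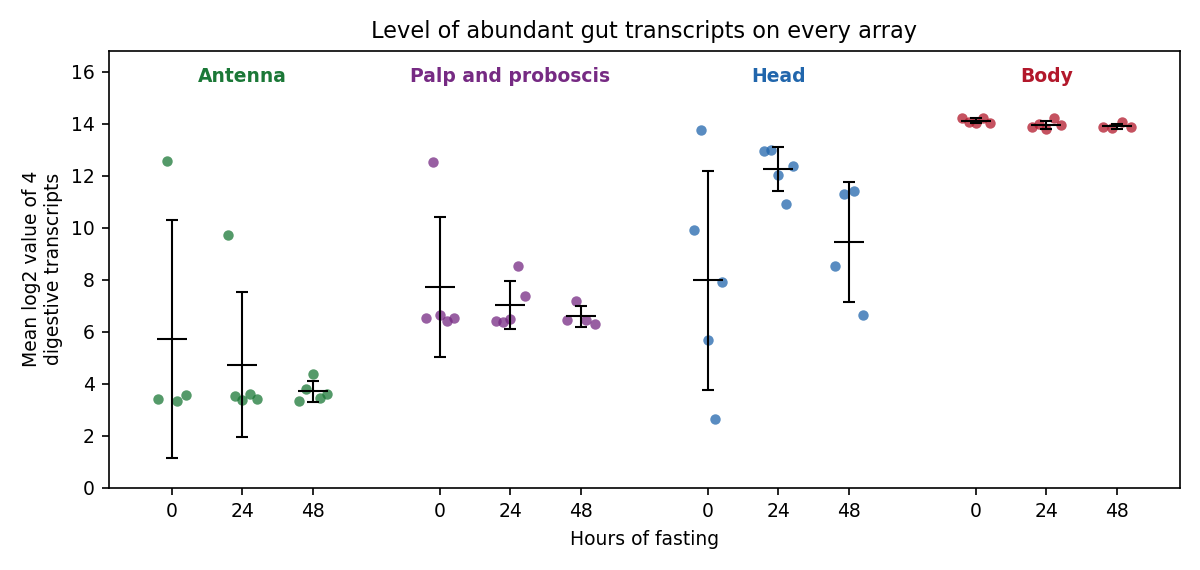
Mean log2 signal of 4 abundant gut transcripts on each array (points) by body part and hours of fasting, with the group mean and SD. Body arrays stayed near 14, and 1 antenna and 1 palp array at 0 h reached 12.57 and 12.53, with head arrays between 2.63 and 13.74.

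Some arrays held transcripts of other organs. The gut level was 12.57 on the 0 h antenna array of replicate 2, where the group minimum was 3.32, and 12.53 on the 0 h palp array of replicate 2, where it was 6.43. The 24 h antenna array of replicate 1 had a gut level of 9.71 and an accessory gland median of 10.29, where the group minima were 3.39 and 2.08. No difference in the gut level between times passed the exact two-sided permutation test in antenna, palp or head (adjusted p from 0.254 to 0.746). The 3′ minus 5′ signal was higher at 24 h than at 0 h in all pools measured at both times in antenna (3), palp (4) and head (4).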

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

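All tests of carried-over RNA and RNA quality in this part were chosen only after the result was seen, and the interaction tests and the counts of other splits were planned. Dixon's test, run on 547 sets of 4 or 5 values, set 38 single values of a gene or of an index apart from the rest of their group, and chance alone sets apart about 1 group in 20.

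The 3′ minus 5′ signal of control transcripts stood apart at 5.14 on the 24 h antenna array of replicate 1, at 5.93 on the 48 h antenna array of replicate 2 and at 5.80 on the 24 h palp array of replicate 5, where the highest other values were 4.00, 3.89 and 3.73. The gut level stood apart at 12.57 on the 0 h antenna array of replicate 2, at 9.71 on the 24 h antenna array of replicate 1 and at 12.53 on the 0 h palp array of replicate 2, against at most 3.55, 3.62 and 6.64. The accessory gland median stood apart at 2.60 (0 h antenna, replicate 2), 10.29 (24 h antenna, replicate 1), 2.82 (0 h palp, replicate 1) and 2.29 (24 h head, replicate 2).

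Single genes stood apart on these arrays. In antenna these were bmm at 24 h (13.15, replicate 2) and, on the 48 h array of replicate 2, CG31102 (10.20), Gr61a (5.85) and ND-B14.5A (11.01). In palp at 0 h it was fit (9.92, replicate 5). In palp at 24 h they were Akh (11.77, replicate 4), sNPF-R (9.24, replicate 1) and, on replicate 2, AkhR (10.65), Gr43a (3.22) and phu (2.52). In palp at 48 h they were bmm (14.06) and Pepck1 (14.56) on replicate 1, Gr66a (7.60, replicate 2) and LysS (5.13, replicate 3). In head at 0 h they were fit (9.26), GstE3 (11.69), Mtk (9.67) and Obp99b (11.32) on replicate 5, all below the others, and Pepck2 (7.48, replicate 2). In head at 48 h they were CG13056 (5.25, replicate 2) and CG43673 (6.04, replicate 3). In body they were Acp76A at 0 h (13.68, replicate 5), Pepck2 at 24 h (7.46, replicate 4) and 48 h (8.22, replicate 3), phu at 24 h (2.64, replicate 3), Jon99Fi (5.35, replicate 3) and Npc2d (5.01, replicate 2) at 48 h, and CG17192 at 24 h (2.08, replicate 5), whose distance from the others lay beyond the second decimal.

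The change with fasting differed between body parts for 2687 features over all times, and at 48 h for 510 (antenna and head), 428 (palp and head), 2286 (body and head) and 514 (antenna and palp). The largest differences of changes were, for antenna minus head, Ama (-5.92), CG43673 (5.64) and hll (-5.31). For palp minus head they were Pgant4 (7.79), Ama (-6.0) and LysS (5.88), and for body minus head mag (-8.45), CG17192 (-7.51) and Npc2d (-7.25). For antenna minus palp they were Pgant4 (-7.04), LysS (-5.88) and CG17290 (5.85). At 0 and 48 h, CG43673 and CG17290 lay below 4 on every antenna array and Npc2d on every head array, and CG17192 averaged 2.99 in unfasted head. A fall could hardly be seen there, so these 4 values restate the fall in the other part. The body parts named by the design are a biological difference that stays open for each of them.

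Digestive enzyme transcripts were called higher as a list in head at 24 h (adjusted p = 0.00437), with 5 of 22 members higher and 1 lower. The call did not hold with an estimated correlation (adjusted p = 0.575), the pool as a block (0.0725) or no filter on dim probe sets (0.0882). Gut RNA carried over during dissection is a candidate explanation: the 22 members moved together within times (mean correlation 0.34), where 1000 random lists of that size had a median of 0 and a highest value of 0.23. Joint regulation in head tissue would give the same co-movement, so the test fits carry-over without excluding the other. Fasting for 24 h may also act on them, and the gut level was higher by 4.27 with an exact permutation p of 0.0635, which leaves it undecided. The gut level ranged from 2.63 to 13.74 among unfasted head arrays, so the 0 h arrays differed by more than that among themselves.

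The lipase gene mag rose at 48 h in palp and head, so carried-over gut RNA was weighed for it. With the gut level as a covariate, its difference was 6.5 ± 0.33 in palp (6.46 ± 0.30 without it) and 4.48 ± 0.50 in head (4.92 ± 0.69 without it, adjusted p = 6.1e-05 with it). RNA that brings the 4 gut transcripts is therefore excluded as the whole source in both parts. Against the level that the gut transcripts allow, mag was in excess by 5.95, 1.38, 2.85 and 5.90 on the 48 h head arrays (mean 4.02). On the 48 h palp arrays mag was 9.42, 9.46, 9.24 and 8.33, where the allowed levels were 1.84, 2.59, 1.84 and 1.68. No array shows a value below 2.08, which lies above the allowed level on palp replicates 1, 3 and 4 and head replicate 4 (2.02). The excess over what could be read is smaller on these arrays. A smaller contribution of carried-over RNA in head, and RNA from gut regions rich in mag and poor in these 4 transcripts, stay open. A rise within palp and head tissue with fasting stays open too, as a hypothesis.

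RNA quality could have shaped the changes called at 48 h in head and body. With the 3′ minus 5′ signal as a covariate, the median ratio of a called gene's difference to its value without it was 0.83 in head and 0.87 in body, and all kept their sign, so this signal is excluded as the whole source. In head 64.2% of the calls held, and in body 48.6%. Over all called genes the median standard error fell from 0.157 to 0.145 in head and grew from 0.173 to 0.204 in body. Over the calls that ended, which are selected for ending, the median ratio was 0.68 in head (standard error 0.159 without and 0.142 with the covariate) and 0.72 in body (0.174 and 0.205). The 3′ minus 5′ signal was higher at 48 h than at 0 h by 1.71 in head (exact permutation p = 0.0952, adjusted p = 0.381) and by 0.38 in body (p = 0.0317, adjusted p = 0.254), with the pools ignored. Within the pools measured at both times it was higher in 3 of 3 in head and in body, too few for a test to pass. How much of the changes follows RNA quality stays open.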

How the results depend on the processing

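Cyclic loess scaling, both covariates, the fits without the 5 set-aside arrays, and list tests under loess or with arrays left out were chosen only after results were seen. Reversals were counted only where a value was called, and there were 0 in any alternative run. Counts not given here stayed within 1.5 times the reported ones. The cause of a moved count was not tested, except that fewer arrays or genes tested enter by construction.

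With no filter on dim probe sets, the counts were 335 for antenna at 24 h, and for 48 h against 24 h they were 1 in antenna, 225 in palp and 53 in head. With the pool as a fixed block they were 273 for antenna at 24 h, 3987 for head at 24 h, 4524 for head at 48 h and 511 for head at 48 h against 24 h. With the pool as a random block they were 38 for antenna at 48 h against 24 h, and 3700, 4321 and 635 for the 3 head comparisons. Array weights gave 1101 for antenna at 24 h, 2832 and 4550 for head at 24 and 48 h, 3804 for body at 24 h, and 45, 1765, 671 and 932 for 48 h against 24 h in antenna, palp, head and body. A single fit over all arrays gave 49, 286 and 1569 for 48 h against 24 h in antenna, head and body, and 3178 for body at 24 h. The 3′ minus 5′ covariate gave 2519 for body at 48 h, and 797, 234 and 338 for 48 h against 24 h in palp, head and body. The gut level as a covariate gave 35 for head at 48 h against 24 h, and leaving out the 5 set-aside arrays gave 5 for antenna at 48 h against 24 h.

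Leaving out each array in turn gave 278 (24 h replicate 2) to 752 (24 h replicate 1) for antenna at 24 h, 1046 (0 h replicate 4) to 1524 for antenna at 48 h, and 1079 (0 h replicate 3) to 2659 (0 h replicate 5) for head at 24 h. It gave 1359 (24 h replicate 2) to 3170 (24 h replicate 1) for body at 24 h. For 48 h against 24 h it gave 0 to 7 in antenna (limma, with 745 at an unadjusted p under 0.05 when all arrays were kept), 90 to 482 in palp, 34 to 114 in head and 269 to 919 in body.

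Of 88 list calls, 0 held with an estimated correlation. The pool as a block kept 74 and added 9, no filter kept 85 and added 24, cyclic loess kept 84 and added 2, and leaving out the 5 set-aside arrays kept 81 and added 3. Quantile scaling again kept 88, added 3 and moved fold changes by at most 0.064, so it says little. Leaving out 1 array gave 81 (antenna 0 h replicate 4) to 93 (palp 48 h replicate 1) list calls.

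For named genes, leaving out 1 array kept the side of the threshold in 3181 of 3372 comparisons, ended a call in 177 (32 of 348 genes and comparisons) and made one in 14. The pool as a block ended 15 of 348 and made 7. No filter ended 28, array weights 4, cyclic loess 7, the 3′ minus 5′ covariate 23, the gut level 13 and a single fit 15.

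Signal over background limits what was seen: between 32.8% and 38.3% of probe sets lay at the lowest value on an array, so changes of dim genes are lower bounds or stay out of view.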

Other observations

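The 3 gene lists weighed here were chosen after genes raised in all 4 body parts had been seen, and their tests on members not yet singled out were set before those results were seen. The counts of other splits were planned.

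Purine synthesis was weighed because Pfas and Gart had risen in all 4 parts. The 7 other members rose as a list at 48 h in 3 of 4 parts. In palp 7 of 7 were called (adjusted p = 0.000386, and 0.0915 with an estimated correlation). In head 5 were (0.00681, 0.0915) and in body 6 (0.00681, 0.336). In antenna 0 were called (limma, with 3 at an unadjusted p under 0.05, list adjusted p = 0.474). Pfas (1.63) and Gart (1.05) rose there and were left out for rising, so this 0 partly follows from that. The 3 list calls fit a shared rise of purine synthesis transcripts during fasting, though none held with an estimated correlation.

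The GATOR and Rag regulators of TORC1 rose as a list in 0 of 4 parts, with 10 other members tested in antenna, palp and head and 9 in body (adjusted p from 0.446 to 0.813). Aminoacyl-tRNA synthetases rose as a list in 0 of 4 parts, with 18 members tested (adjusted p from 0.446 to 0.813).

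Other splits of the same arrays, 100 for each count with the real one included, were fitted alike, and with the pools ignored chance can be excluded at a share of 0.05 for each. As many features as in the real split came from 1 split, the real one, for palp at 24 h (2124, highest other 98), 48 h (2986 and 2449) and 48 h against 24 h (381 and 154), antenna at 48 h (1580 and 524), head at 48 h against 24 h (124 and 21), and body at 24 h (1977 and 57) and 48 h (4742 and 2720). They came from 2 splits for antenna at 24 h (515 and 541) and 48 h against 24 h (9 and 13) and for head at 24 h (1564 and 2334) and 48 h (2318 and 3341), and from 3 for body at 48 h against 24 h (601 and 2154). The last count, several times the real one, points to a structure of the body arrays, which was not identified. Between 10 and 22 of the splits part as many pools as the real one. Among these, head at 48 h was reached by 2 of 22 (the other with 3341), so chance is not excluded there with the pools heeded either. The other comparisons had at most 20, too few for a share under 0.05. Among comparisons of times, their highest were 524, 2449 and 1762 in antenna, palp and body at 48 h, 477 in head and 57 in body at 24 h, 154 in palp at 48 h against 24 h, and at most 7 elsewhere. Head at 48 h had 4524 features with the pool as a block. The unfasted comparisons with head gave 5485 (antenna, highest other 4415), 6040 (palp, 3440) and 9625 (body, 7320), each from 1 split. Exchanging body parts gave at most 9 features for the F test (real 2687), and 1254 for antenna and head (real 510, reached in 2 of 100), 228 for palp and head (428), 1157 for body and head (2286) and 211 for antenna and palp (514). Regrouped times gave at most 77 list calls, against 88, so single calls are weak evidence.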
